A study of Mus musculus with 2 samples.

How the data were processed

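Transcripts of sorted innate lymphoid cells from mouse lung tumours were counted in 2 single-cell libraries, 1 per genotype. The deposited files hold raw counts, that is, whole numbers of molecules per cell and gene after correction of molecular identifiers, and all values were found to be whole and not negative. The authors made these counts with the BD WTA Multiplex Rhapsody Analysis Pipeline, version 1.8, per the file headers. Those headers name a human reference (GRCh38 with GENCODE 29) and human sample tags, while the gene columns carry mouse symbols and the submitters' processing notes name mm10; 99.3% of the 24794 symbols were found in the mouse annotation GENCODE M21. The aligner and the cell-calling settings are not given in the sources used here. Per the labels' protocols, only samples with high viability were sequenced and each genotype had its own cartridge.

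The groups follow the titles and source names of the libraries. The tissue field of each library gives the opposite genotype, so every direction is stated for the library labelled WT or the library labelled KO. The files list 22406 gene columns for the library labelled WT and 22373 for the library labelled KO, with 19985 in both, and a gene without a column was given 0 molecules. Each file also has 2 lines without a cell barcode, with 283 and 69 molecules, which were left out.

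Cells with at least 500 molecules, at least 200 genes and at most 25% mitochondrial molecules were kept. That left out 80 cells (1.01%) of the library labelled WT and 271 (3.63%) of the library labelled KO. Scrublet, run per library in scanpy 1.11.5, marked 5 and 2 cells, under 0.5% of either library. It was therefore taken as not having worked, and no cell was left out as a doublet.

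Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen per library without Ccrl2, mitochondrial, ribosomal protein, Xist and Y-linked genes, entered 30 principal components. A graph of shared neighbours over 15 neighbours was clustered by the Leiden method at resolution 1.0 on both libraries together, with no integration (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). Clusters were named from marker lists fixed before the data were examined. The scoring thresholds were set after the clusters were seen. A cluster took a name where the mean log2 fold of that type's markers over all other cells was at least 1 and led the next type by 0.5, with at least 3 markers at 2-fold or more and 50 CPM (summed molecules scaled to a common total), after 10 CPM were added to both sides. Because most cells were NK-like, NK markers were instead compared with the cells of the clusters that had been given another type or left unnamed. Under that reference each NK-like cluster had at least 3 NK markers and 0 markers of another type among its 10 leading genes. Against all other cells, the NK-like cluster led by Tcf7 had 0 NK markers there. It had 1 marker each of monocytes/macrophages (Ccr2), T cells (Cd28) and ILC1 (Cd7), so values without that cluster were also computed. These thresholds kept 36 and 55 cells with Cd3e, Cd3g, Icos and Cxcr6 among their leading genes out of the T cell-like class.

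Molecules were summed per library and class, divided by the class total, and compared as a log2 ratio of the library labelled KO over the library labelled WT. The plan named NK-like, ILC1-like and ILC2-like cells for this comparison, each only with at least 100 cells per library. It also asked that no cluster of a class have more markers of another type than of its own among its leading genes. NK-like cells met this only under the NK marker reference above, which was set after the clusters were seen. With all other cells as the reference, the cluster led by Tcf7 did not meet it. Of the planned classes, NK-like and ILC2-like cells had enough cells and were compared, over genes with at least 100 summed molecules. Tests of explanations also used summed ratios of other classes, most of them below the minimum of 100 cells. A count of 0 beside more than 3 molecules was set to a floor of 3, and no ratio was computed where both counts were at or under 3. No test was run, because each genotype had 1 library and cells are not replicates. Intervals are 95% intervals for counting error only: exact Poisson for molecules, exact binomial (Clopper-Pearson) for shares, Newcombe's for differences of shares, and conditional binomial for ratios. Intervals of list medians come from 1000 Poisson draws.

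Named genes followed a rule fixed before the data were examined. For NK-like cells it took the 12 highest and 12 lowest log2 ratios among genes with at least 200 summed molecules and 50 CPM in the higher library. For ILC2-like cells it took 6 and 6. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Xist and Y-linked genes and unnamed gene models were left out. The rule also took up to 4 members of each fixed list with the largest absolute ratios, and Ccrl2, Cmklr1, Ncr1, Ifng, Gzmb, Itgam, Cd27, Il5, Il13 and Areg. Gene lists were fixed at the same time. They covered mature NK, immature NK, cytotoxic effectors, NK cytokines and chemokines, chemoattractant receptors and adhesion, activating receptors, inhibitory receptors, tissue residency and TGF-beta response, type I interferon response, immediate early and dissociation stress, glycolysis and hypoxia, mTORC1 and MYC targets, cell cycle, exhaustion and regulatory transcription factors, ILC2 cytokines, ILC2 receptors and regulators, flanking genes of Ccrl2, X-inactivation and Y-linked genes, mitochondrial genes and ribosomal protein genes. A list's members were measured at 50 or more summed molecules. Its median was placed among 10000 random lists matched on expression. Genes of random lists were drawn independently, so the percentile ignores genes that vary together and does not cover spread between libraries. Members were called higher or lower at 1.25-fold or more, the size rule for members, with an interval that excluded no difference.

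Shares of NK-like cells with a molecule of a gene were compared after every cell was thinned to 1324 molecules, the 10th percentile of NK-like cells in the shallower library. The thinning was drawn again 20 times after the data were seen. The ratio, size rule and list median were tested on counts simulated from the means of all kept cells over 10047 genes. There, 98.5% of genes changed 2.5-fold and 100% of those changed 4-fold passed 2-fold, as did 0% of those changed 1.25-fold and 0% of the 9847 unchanged genes, and 95.4% of intervals held the true ratio. The simulated counts were Poisson draws at the depth of all kept cells. They check the computation, not added spread between cells or the fewer molecules of single classes. Alternatives covered the cell filters, clustering settings, denominators, scaling, count minimums, thinning and cell weights. Leaving out the cells with the highest 5% of doublet scores and leaving out groups of NK-like clusters were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.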

Results

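Innate lymphoid cells were sorted from lung tumours of mice with mutant Kras and deleted p53, and their transcripts were counted cell by cell. Tumours had been started by intranasal adenovirus carrying Cre recombinase (25000000 infectious particles) at 8 weeks of age, and the lungs were taken 10 weeks later. There were 2 libraries, 1 labelled Ccrl2 wild type (WT) and 1 labelled Ccrl2 knockout (KO). Ccrl2 encodes an atypical receptor that binds the chemoattractant chemerin, and the series asks what it contributes to NK cell recruitment in the lung. The library labelled WT held 7905 cells and 19892009 molecules, and the library labelled KO held 7461 cells and 16079206 molecules. After filtering, 7825 and 7190 cells remained, with medians of 2270 and 2042 molecules and 1232 and 1134 genes per cell. Each genotype was run on its own cartridge, so genotype and cartridge cannot be told apart, and the number of mice per library is not given in the sources used here. No difference below has a replicate check. Intervals are 95% intervals that cover counting error only.

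The targeted gene was far lower in the library labelled KO. Ccrl2 lies on the minus strand of chromosome 9 from 111054486 to 111057519 (mm10). Kept cells of the library labelled WT held 492 Ccrl2 molecules, or 24.8 CPM (22.6 to 27.1; molecules scaled to a common total), against 28 molecules, or 1.75 CPM (1.16 to 2.53), in the library labelled KO. This was a 14.1-fold difference (9.66 to 21.5). At least 1 Ccrl2 molecule was seen in 406 cells (5.19%) and 26 cells (0.362%). These counts go with the title and source name of each library and against its tissue field, which gives the opposite genotype. The sources used here do not say which part of the gene was deleted, so the molecules that remained cannot be assigned to intact or altered transcripts.

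Among cell classes of the library labelled WT, Ccrl2 was highest in monocyte/macrophage-like cells, at 207 CPM (151 to 276), from 46 molecules in 11 of 35 cells. It stood at 23.3 CPM (21.03 to 25.6) in NK-like cells and 22.4 (12.5 to 36.9) in ILC2-like cells, and B cell-like cells held 1 molecule. In the library labelled KO the monocyte/macrophage-like value was 13.5 CPM (1.64 to 48.8), from 2 molecules. NK-like cells held 400 molecules in the library labelled WT and 21 in the library labelled KO, a log2 ratio of -3.93 (-4.63 to -3.29).

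**Figure D1:**
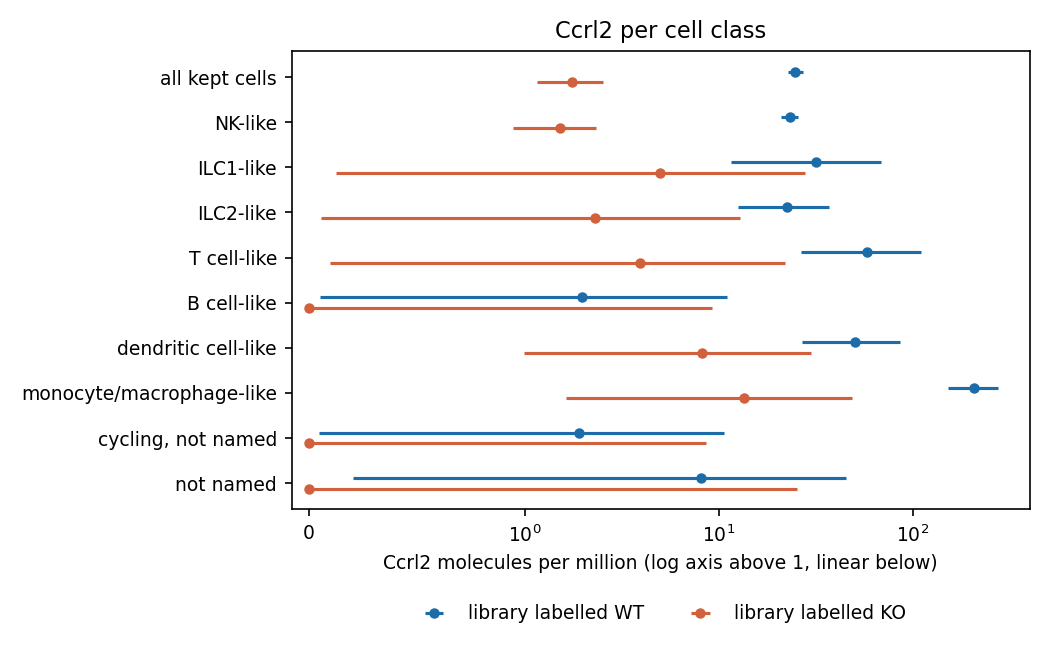
Ccrl2 CPM (horizontal axis, logarithmic above 1) in each cell class, for the library labelled WT (blue) and the library labelled KO (orange), with exact Poisson 95% intervals. Over all kept cells the values were 24.8 and 1.75.

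NK-like cells, led by Ly49 receptor genes such as Klra8 together with Prf1 and Gzma, made up nearly all cells of both libraries. They were 91.7% (91.0 to 92.3) of kept cells in the library labelled WT and 89.9% (89.2 to 90.6) in the library labelled KO, a difference of -1.78 points (-2.71 to -0.853). ILC2-like cells, with Il1rl1 (the IL-33 receptor) and Arg1, were 2.40% (2.07 to 2.77) and 2.21% (1.88 to 2.58). ILC1-like cells, with Cxcr6 and Itga1, were 0.895% (0.698 to 1.13) and 1.08% (0.858 to 1.35). The intervals of both differences included 0. No cluster met the markers of ILC3. Of the NK-like, ILC1-like and ILC2-like cells together, NK-like cells were 96.5% in both libraries.

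The rest held cells of other lineages and cycling cells, although the design describes a gate on NKp46 and CD127. T cell-like cells, with Cd8a and Cd3e, were 0.690% (0.519 to 0.899) and 1.42% (1.16 to 1.72), a difference of 0.729 points (0.404 to 1.07). A cluster with Cd3e, Cd3g and Icos that stayed unnamed under thresholds set after the clusters were seen held 0.460% and 0.765%. B cell-like cells were 1.84% (1.55 to 2.16) and 2.46% (2.12 to 2.85), a difference of 0.621 points (0.158 to 1.09). Dendritic cell-like cells were 0.601% and 0.709%, monocyte/macrophage-like cells 0.447% and 0.473%, and cycling cells without a type 0.997% and 0.987%. The cycling cells carried the NK gene Ncr1 at 568 and 567 CPM, against 41.4 and 65.1 in B cell-like cells, so they were not shown to be of another lineage. Shares after a sort reflect the gate and the loading of each cartridge, and do not measure numbers of cells in the lung. When each library was clustered alone, the T cell-like difference was 0.323 points.

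**Figure D2:**
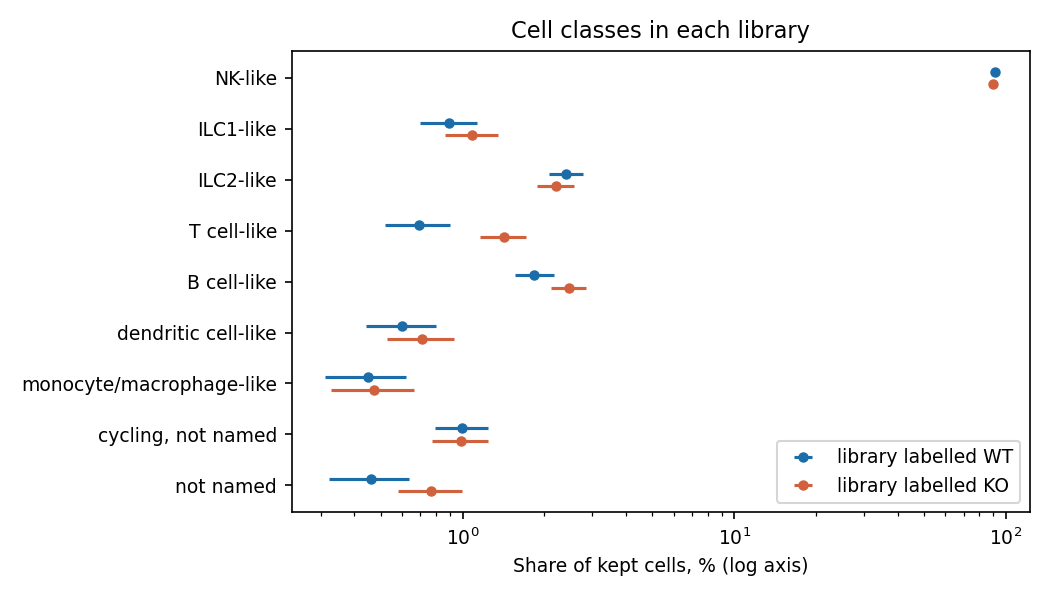
Share of kept cells in each class (horizontal axis, percent, logarithmic) in the library labelled WT (blue) and the library labelled KO (orange), with exact binomial 95% intervals. NK-like cells were 91.7% and 89.9%.

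Within NK-like cells, expression of most genes was close in the 2 libraries, and heat shock and stress genes stood among the largest differences. Among genes open to the naming rule, which leaves out gene models and genes of low counts, the highest ratio in the library labelled KO was that of Kcnip3 (chromosome 2, 127456498 to 127522094), a calcium-binding transcriptional regulator, at a log2 ratio of 1.24 (1.09 to 1.40), at 31.0 CPM in the library labelled WT and 73.3 in the library labelled KO. Next among them were the inducible heat shock proteins Hspa1a at 1.09 (0.96 to 1.22) and Hspa1b at 0.73 (0.65 to 0.81), neighbours on chromosome 17. Their sequences are nearly identical, so the split between them is uncertain. Cpt1a, which carries fatty acids into mitochondria, had 0.71 (0.59 to 0.83), and Gpx4, which reduces lipid peroxides, 0.49 (0.41 to 0.56). The other genes the rule named as higher were Wsb1 (0.48), Eif3g (0.46), Hmgn2 (0.43), Klf4 (0.41), Csrnp1 (0.41), Pgls (0.40) and Sertad2 (0.39).

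Among the same genes, to which Ccrl2 does not belong by its counts, the lowest was S100a4 (chromosome 3, 90603771 to 90606045), a calcium-binding protein linked to cell motility, at -0.65 (-0.81 to -0.48). It was followed by the kinase Gsk3a at -0.46 (-0.54 to -0.38), the fatty acid desaturase Scd2 at -0.44 (-0.55 to -0.33) and Triobp at -0.44 (-0.58 to -0.30). Uqcr10 (-0.40) and Cox17 (-0.39), both of the mitochondrial respiratory chain or its assembly, were also among the lowest, with Lrrfip2 (-0.41), Ap1b1 (-0.39), Clptm1 (-0.38), Impdh1 (-0.38), Ptpn18 (-0.34) and Fcho1 (-0.34). Among genes named in advance, Cmklr1, the signalling receptor for chemerin (chromosome 5, 113612354 to 113650426), stood at 130 and 116 CPM, a log2 ratio of -0.16 (-0.25 to -0.066). The activating receptor Ncr1 (-0.039), Ifng (-0.018), Gzmb (0.050) and Itgam (0.054) lay near 0, and Cd27 was at -0.25 (-0.43 to -0.069). Il5, Il13 and Areg had at most 5 molecules in either library.

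By the size rule, 8 of 9381 genes were at least 2-fold higher in the library labelled KO and 4 were at least 2-fold lower. The comparison rested on 7173 and 6463 cells and 17201884 and 13726377 molecules. The genes higher were Kcnip3, Hspa1a, the endosomal GTPase Rab4a (1.18), the transcription factor Maff (1.10), Tmem51 (1.09) and the gene models Gm17399 (1.18), Gm4707 (1.08) and Gm9844 (1.02). The genes lower were Ccrl2, the mismatch repair gene Mlh1 (-1.82), the peptide transporter Slc15a2 (-1.49) and Usp50 (-1.10). Usp50 lies near Kcnip3 on chromosome 2, at 126709096 to 126783470. Apart from Ccrl2, Kcnip3 and Hspa1a, the genes of both groups were picked out after their values were seen. With 500 summed molecules as the minimum the counts were 4 and 0. Thinned to a common depth, 6 genes were higher and 3 lower, and over 20 further random thinnings 1 to 5 and 3 to 6. Without the clusters led by stress genes, 3 were higher. Those clusters had Atf3, Hspa1a or Egr3 among their first 3 genes over all other cells, so the cluster led by Ly6c2 and Hspa1b was kept. The median log2 ratio over all genes was -0.00074, and the SD was 0.12 among 4729 genes with at least 1000 molecules. Across genes, which are not independent replicates, the libraries had r = 0.996 on the log2 scale. The largest NK-like cluster was a different one in each library. It was that led by Klra10 over all other cells in the library labelled WT, with 23.6% of NK-like cells. In the library labelled KO it was that led by Ly6c2 and Hspa1b, with 23.3%. The latter was the shallowest NK-like cluster, at a median of 1645 molecules against 2149. Cells were not thinned before clustering, and the library labelled KO was the shallower, so depth may have shaped these clusters.

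**Figure D3:**
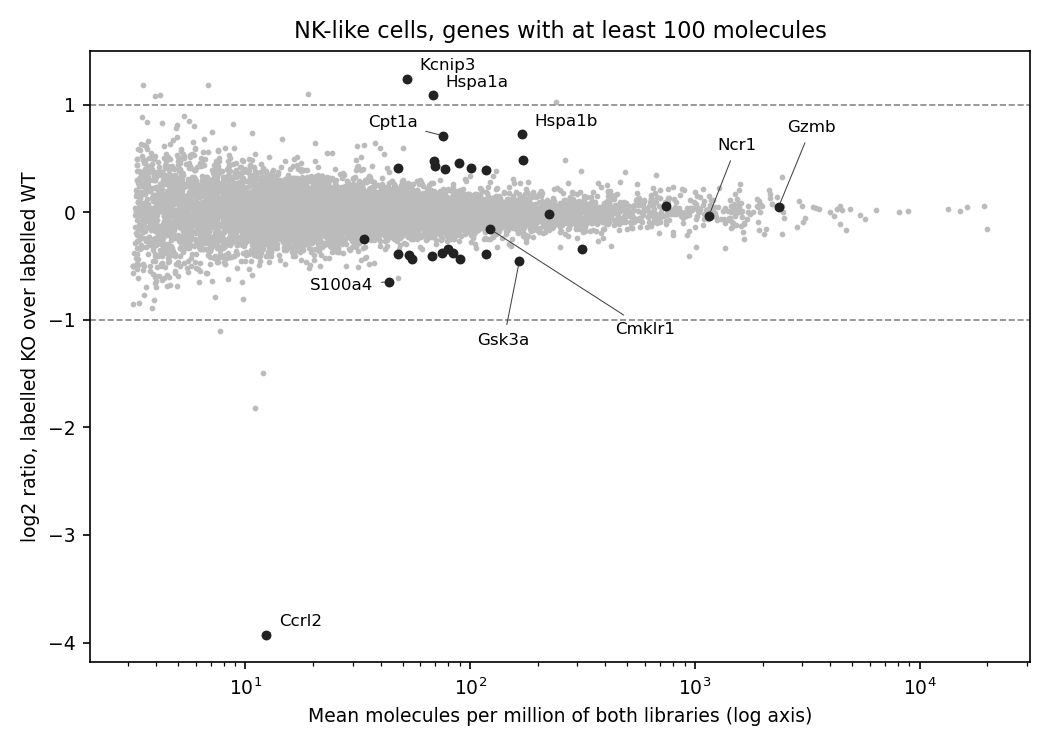
Log2 ratio of the library labelled KO over the library labelled WT (vertical axis) against mean CPM (horizontal axis, logarithmic) for genes in NK-like cells. Black points are genes named by the fixed rule, dashed lines mark 2-fold, and Ccrl2 lies at -3.93.

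Of the fixed gene lists in NK-like cells, immediate early and dissociation stress genes had the highest median apart from sex-linked and Ccrl2-flanking genes. Their median log2 ratio was 0.11 (0.067 to 0.14), above all 10000 random lists. Of 23 measured members, 3 were higher and 0 lower: Hspa1a, Hspa1b and the transcription factor Atf3 (0.60). Nfkbia, an inhibitor of NF-kB, had 0.27. NK-like cells of the library labelled KO lay more in the clusters led by Atf3 and Nr4a2 (14.99% in the library labelled WT and 19.6% in the library labelled KO) and by Hspa1a and Hspa1b (1.62% and 2.92%). Without these and the cluster led by Tnfrsf9 and Egr3 (5.34% and 4.98%), but with the cluster led by Ly6c2 and Hspa1b kept, the list median was 0.080. Cytotoxic effectors had a median of 0.063 (0.038 to 0.085), above 97.9% of random lists, with 0 of 16 members higher or lower by the size rule for members; Ctsw had 0.13 and Gzmm 0.27 (-0.025 to 0.56). Without the cluster led by Tcf7 their median was 0.042. Inhibitory receptors had 0.067 (0.036 to 0.14), above 97.3%, with 1 of 12 members higher, Tigit at 0.34, and Klra8 at 0.21; their median was 0.11 without the cells of highest doublet scores.

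Chemoattractant receptors and adhesion genes had a median of -0.082 (-0.12 to -0.034), above 0.160% of random lists. Of 20 members, which include Ccrl2 itself, 2 were lower and 0 higher: Ccrl2 and the chemokine receptor Cxcr3 (-0.33). The lymphocyte egress receptor S1pr1 had -0.30 (-0.42 to -0.17). The list median was -0.041 with 500 molecules as the minimum for members and -0.032 without the cluster led by Tcf7. It was also -0.041 in the setting with 20 molecules as the minimum for genes, where every member with a ratio entered. Type I interferon response genes had -0.090 (-0.13 to -0.0098), above 0.810% of random lists, with Ifit1 (-0.85) and Rtp4 (-0.34) lower and Oas1a (0.40) higher among 20; their median was -0.036 with equal weight per cell and -0.041 without the cluster led by Tcf7. Activating receptors had -0.042 (-0.059 to -0.014), with 0 of 18 higher or lower, and -0.022 without the clusters led by stress genes.

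The NK maturation lists lay near 0. Mature NK genes had 0.012 (-0.023 to 0.040) with 0 of 13 higher or lower by that rule, although S1pr1 (-0.30) and Cx3cr1 (-0.16) lay below 0 and Ly6c2 (0.27) and Irf8 (0.17) above. Immature NK genes had -0.0082 (-0.075 to 0.020) with 2 of 14 lower, Socs2 (-0.58) and Cxcr3. Medians were -0.019 for NK cytokines and chemokines, where Ccl9 (0.34) was higher, -0.023 for tissue residency and TGF-beta response, 0.00026 for glycolysis and hypoxia, and -0.00083 for mTORC1 and MYC targets, where Odc1 (0.38) was higher and Slc7a5 (-0.38) lower. They were -0.055 for the cell cycle, 0.022 for exhaustion and regulatory transcription factors, where Batf (-0.37) was lower, 0.052 for ILC2 cytokines and -0.0042 for ILC2 receptors. Genes flanking Ccrl2 had 0.11 (-0.068 to 0.14), and -0.0056 when thinned. That list does not include Lrrfip2 (-0.41) and Mlh1 (-1.82), which start at 111117592 and 111228228 on chromosome 9, past the end of Ccrl2. Its members with the largest absolute ratios, Elp6, Pth1r, Smarcc1 and Nradd, all lie on the other side of Ccrl2. Mitochondrial genes had -0.029 (-0.037 to -0.0041) and ribosomal protein genes 0.016 (0.0054 to 0.029). Of the latter, Rps15a (-0.41), Rpl37 (-0.33) and Rpl31 (-0.32) were lower. The means of the tissue residency (0.039) and ribosomal protein lists (-0.00068) had the sign opposite to their medians. X-inactivation and Y-linked genes had a median of 0.49 (0.30 to 0.58), with 4 of 6 members, all Y-linked, higher.

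**Figure D4:**
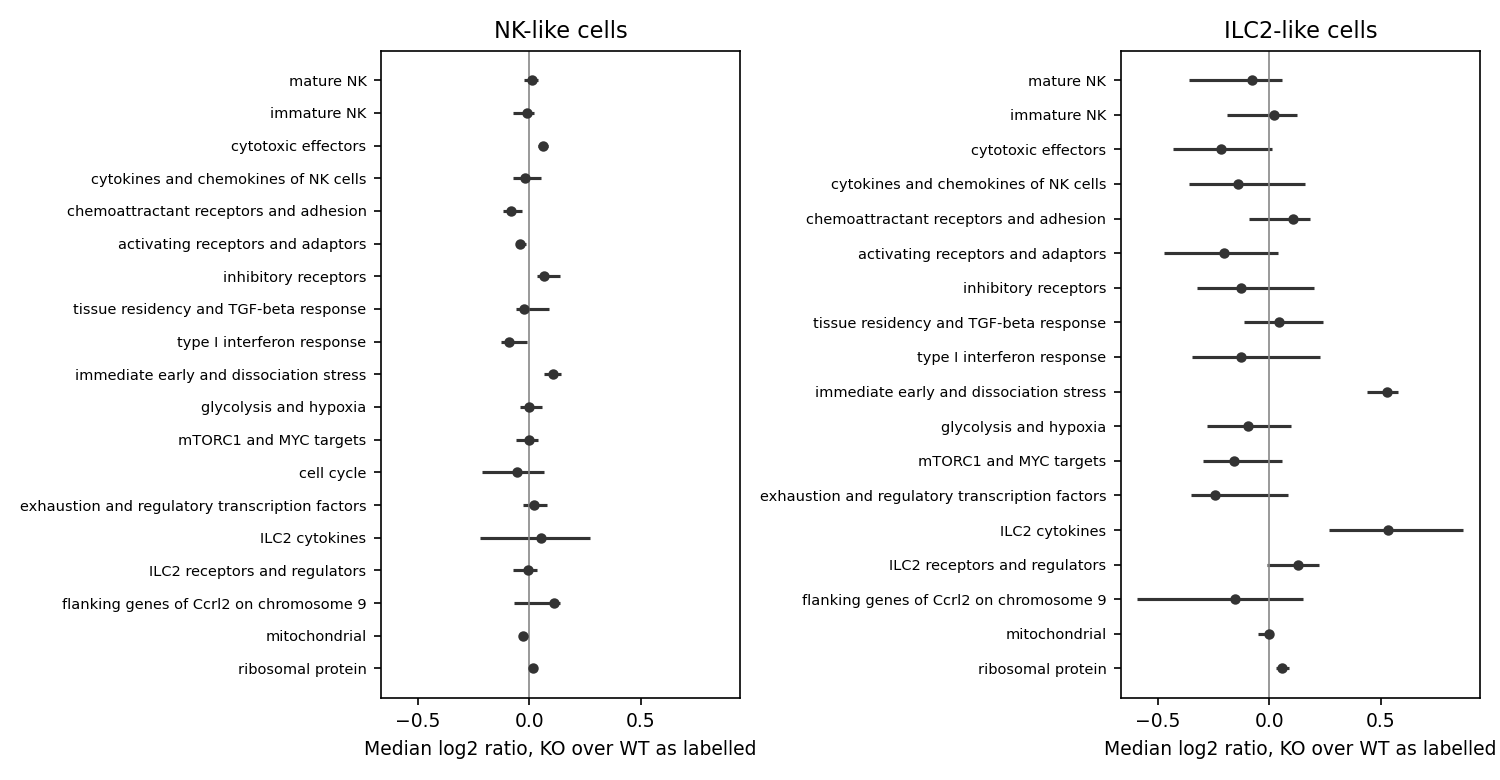
Median log2 ratio of the library labelled KO over the library labelled WT (horizontal axes) for the fixed gene lists in NK-like cells (left) and ILC2-like cells (right), with 95% counting intervals; the list of sex-linked genes is not drawn. The stress list stood at 0.11 and 0.53.

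After every NK-like cell was thinned to 1324 molecules, which left out 300 and 645 shallower cells, the share with a Cmklr1 molecule was 15.7% (14.8 to 16.6) and 14.3% (13.4 to 15.3). Over 20 further draws it was lower in the library labelled KO in all, by between -2.25 and -1.12 points. Unthinned, the shares were 24.97% and 20.4%, at median depths of 2226 and 2014 molecules. Itgam, an integrin of mature NK cells, was seen in 56.9% (55.7 to 58.1) and 58.3% (57.0 to 59.6), while the unthinned shares, 72.7% and 69.7%, had the opposite order; over the further draws the difference ran from -0.337 to 1.51 points. Thinned shares were 81.8% and 81.4% for Gzmb, 35.1% and 34.8% for Klrg1, 21.9% and 20.95% for Ifng and 3.91% and 3.73% for Cd27. The unthinned shares of these genes were 88.7% and 85.2%, 47.0% and 43.5%, 31.5% and 28.7%, and 7.35% and 5.51%. B cell-like cells, which should lack these NK genes, showed thinned shares of 2.86% and 1.31% for Itgam, 3.57% and 6.54% for Gzmb, 0% and 1.31% for Klrg1 and Ifng, and 0% and 0.654% for Cmklr1, at unthinned median depths of 2523 and 1954 molecules. Cd27 was seen in 0 of the thinned monocyte/macrophage-like cells, which allows a share of up to 10.3% and 12.3%. Itga1 (0.960% and 0.928%) was within the range of the B cell-like background, and Cxcr6 was near 0 (0.0727% and 0.0516%; unthinned 0.112% and 0.124%, and 1.59% and 1.24% for Itga1).

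ILC2-like cells showed higher levels of some ILC2 cytokine genes and of many immediate early genes in the library labelled KO. The direction for Il5 depended on the draw when cells were thinned. The ILC2 cytokine list had a median log2 ratio of 0.53 (0.27 to 0.87), above all 10000 random lists, with 4 of 7 measured members higher and 0 lower. Those were Calca, which encodes the neuropeptide CGRP, at 1.14 (0.66 to 1.63), the epithelial growth factor Areg at 0.97 (0.58 to 1.35), Il5, an eosinophil growth factor, at 0.53 (0.0063 to 1.06), and Csf2 at 0.51. Il13 had 0 molecules in the library labelled WT and 7 in the library labelled KO, a log2 ratio of 1.85 against the floor of 3 counts. The immediate early and dissociation stress list had 0.53 (0.44 to 0.58), with 13 of 20 members higher and 0 lower, such as Egr1 at 1.41 (0.99 to 1.83), Atf3 at 1.39 and Zfp36 at 0.68. ILC2 receptors and regulators had 0.13 (-0.0090 to 0.22), with 3 of 17 higher: Ly6a (0.54), Tnfrsf18 (0.54) and Il1rl1 (0.42).

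The 6 highest named genes in ILC2-like cells were Egr1, Klf4 (1.10), Areg, Gpx4 (0.81), Nfkbiz (0.77) and Gpr132 (0.76). The 6 lowest were the helicase Dhx9 (-0.82), the integrin adaptor Tln1 (-0.71), Arl4c (-0.71), Bin2 (-0.65), Cast (-0.61) and Lpar6 (-0.61). Of 2000 genes compared, 4 were at least 2-fold higher and 5 lower. This class held 188 and 159 cells with 671025 and 434734 molecules, at median depths of 3279 and 2524 molecules. When every cell was thinned, Il5 had -0.070, Areg 0.54 and Il13 0.71 against the same floor. Over 20 further thinnings Il5 ran from -0.17 to 0.82 and Areg from 0.45 to 1.34.

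RNA of NK genes was also counted in ILC2-like cells. Gzma stood at 930 and 899 CPM there, against 473 and 819 in B cell-like cells, which should lack it, so in the library labelled KO the level was close to that background. Several NK genes were lower in the library labelled KO: Ncr1 at -0.997 (-1.71 to -0.33), the chemokine Ccl4 at -2.28 (-3.20 to -1.47), Ly6c2 at -1.23 and Cd27 at -0.96, while Gzmb had -0.34 (-0.75 to 0.064), Itgam 0.63 (-0.052 to 1.30) and Ifng 0.041. Cytotoxic effectors had a median of -0.21 (-0.43 to 0.014) and activating receptors -0.20 (-0.47 to 0.040). The remaining medians were -0.076 for mature NK genes, 0.020 for immature NK genes, whose mean was -0.27, -0.14 for NK cytokines, 0.11 for chemoattractant receptors, of which 4 of 14 were lower, such as Sell (-0.98), and 1 higher, -0.12 for inhibitory receptors, 0.045 for tissue residency, -0.13 for type I interferon, -0.094 for glycolysis, -0.16 for mTORC1 and MYC targets, -0.24 for exhaustion factors, -0.15 for genes flanking Ccrl2, 0.0014 for mitochondrial genes, whose mean was -0.036, and 0.059 for ribosomal protein genes. Without the cells of highest doublet scores, the mature NK and cytotoxic medians were 0.47 and 0.37. Fewer than 3 genes of the cell cycle list and of the sex-linked list were measured, so these lists have no median. Of the sex-linked genes, the Y-linked Ddx3y had 1.28 (0.45 to 2.14) and Xist -0.49 (-0.74 to -0.24). The mix of male and female cells may thus differ between the libraries in this class. Its part in the other differences was not tested. Ccrl2 itself had 15 molecules and 1, and Cmklr1 2 in each library.

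Expression was not compared within ILC1-like cells, of which there were 70 and 78.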

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

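All checks in this part were chosen after the data were seen. Molecules of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, summed over all kept cells, were found in both libraries. There were 1451 in the library labelled WT (73.1 CPM) and 1714 in the library labelled KO (107 CPM). Xist, expressed from the inactive X chromosome, stood at 276 and 262 CPM, so both libraries held transcripts of male and of female cells. No explanation of the difference in Y-linked molecules was tested, and the labels give no sex.

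Lines without a cell barcode held 283 molecules in the library labelled WT and 69 in the library labelled KO. They entered no comparison.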

How the results depend on the processing

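Most alternatives were planned; leaving out high doublet scores or groups of NK-like clusters, and the 20 repeat thinnings, were chosen after the data were seen. No paired analysis was possible because each genotype had 1 library. Keeping called doublets was not run, since none had been left out, and the ILC2 cytokine list had too few members at 500 molecules. Changes of sign were counted only for values whose main interval excluded 0. Of 398 values for shares, counts, list medians and Ccrl2, 367 stayed within the counting interval or within 1.5 times the count, 31 did not, and 0 so counted changed sign. Medians with an interval that included 0 did change sign, such as those of mature NK and cytotoxic genes in ILC2-like cells without high doublet scores. Of 454 for single genes, 433 stayed within, 20 did not, and 1 so counted changed sign: Il5 in ILC2-like cells, at -0.070 when thinned.

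Clustering each library alone gave a T cell-like difference of 0.323 points, and innate lymphoid cells alone an NK-like difference of -0.0654 points. At 20 summed molecules 96 genes were 2-fold higher and 40 lower, and at 500, with fewer genes compared, 4 and 0. Thinning gave NK-like medians of -0.030 for mature NK, 0.078 for NK cytokines, -0.12 for chemoattractant receptors, -0.060 for glycolysis, 0.049 for mTORC1 and MYC, -0.044 for mitochondrial and 0.043 for ribosomal protein genes, and ILC2-like medians of -0.45 for type I interferon and 0.43 for stress genes. Other draws differed: chemoattractant receptors ran from -0.10 to -0.012 and mature NK genes from -0.034 to 0.020. Equal weight per cell gave 0.034 for immature NK genes and, in ILC2-like cells, -0.51 for activating receptors. Without high doublet scores, ILC2-like medians were 0.47 for mature NK and 0.37 for cytotoxic genes. Without the cluster led by Tcf7, NK-like medians were 0.050 for immature NK, -0.048 for glycolysis and 0.61 for sex-linked genes. Without clusters led by stress genes, but with that led by Ly6c2 and Hspa1b kept, 3 genes were 2-fold higher. Medians were then 0.022 for immature NK and 0.033 for ribosomal protein genes. Unthinned shares differed by -3.05 points for Itgam, -1.84 for Cd27, -3.55 for Klrg1, -4.53 for Cmklr1, -2.83 for Ifng and -3.59 for Gzmb, the library labelled WT being deeper. Otherwise the cause was not tested.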

Other observations

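The tests of shared barcodes, of wild-type cells, of NK-like cells alone, of genes of like length and GC content and of DNA around Ccrl2, and the comparison of stress genes over all classes, were chosen after the results were seen; the tests of depth, of B cell-like cells and of a trend on transcript length and GC content were set before.

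Cmklr1, the signalling receptor for chemerin, and Ccrl2 had different distributions over the cell classes. In the library labelled WT, Cmklr1 stood at 130 CPM in NK-like cells and 85.4 (51.4 to 133) in monocyte/macrophage-like cells, but ILC1-like and ILC2-like cells held 2 molecules each. Cycling cells without a type had 43.7 (27.7 to 65.6) and 44.5 (26.8 to 69.5) CPM in the libraries labelled WT and KO, with a molecule in 23.1% and 21.1% of cells. Ccrl2 in the library labelled WT was 57.9 CPM (26.5 to 110) in T cell-like and 50.5 (26.9 to 86.3) in dendritic cell-like cells. Apart from NK-like and ILC2-like cells, each class in this paragraph had fewer than 100 cells in the library labelled WT.

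A few Ccrl2 molecules remained in the library labelled KO. Of the 27 barcodes that carried them, 1 was also present in the library labelled WT, and 0 carried Ccrl2 in the library labelled WT, so at most 12.8% could have, which argues against molecules that moved between libraries with their barcode. A share of wild-type cells in the pool stays open: it predicts the same ratio in every class, and the log2 ratio was -3.48 (-4.83 to -2.38) outside NK-like cells against -3.93 within them. With 7 molecules outside NK-like cells the test was too weak to decide, and transcripts from an altered allele cannot be told apart from it.

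The median of the immediate early and stress list was above 0 in NK-like cells, where 3 of 23 members were higher in the library labelled KO, and in ILC2-like cells, where 13 of 20 were. In thinned NK-like cells the list median was 0.12 (0.069 to 0.17), and over 20 further draws it lay between 0.074 and 0.13. By the prediction set before, that spoke against a difference in depth. The test cannot exclude depth, however, since random thinning keeps each gene's expected share of a cell's molecules. Different handling of the cartridges may have raised these genes, since B cell-like cells, where the prediction was set before, had a median of 0.20 (0.091 to 0.29). It stays open because classes with few cells went both ways, monocyte/macrophage-like (0.16) and unnamed cells (0.26) with B cell-like cells, and T cell-like (-0.30), dendritic cell-like (-0.34), cycling (-0.27) and ILC1-like cells (-0.19, -0.25 to 0.024) against them; that classes other than B cell-like could keep the question open was decided after their values were seen. An effect of the genotype also stays open, since each genotype had its own cartridge.

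The differences of the 24 genes named by rank in NK-like cells were not confined to that class; larger ones in genes of lower counts, such as Mlh1, were not part of this test. Signed by their direction in NK-like cells, those genes had a median log2 ratio of 0.36 (0.25 to 0.52) in B cell-like, T cell-like, dendritic cell-like and monocyte/macrophage-like cells, with 52 of 72 pairs of gene and class with at least 20 molecules in the same direction. That argues against a change in NK-like cells alone; free RNA of NK-like cells may add to it, although Gzma in those classes was 2.87% and 7.65% of its NK-like level. Removing a trend on transcript length and GC content left 0.996 of the median absolute ratio but decides nothing, since the trend was nearly flat. The 100 genes nearest in length and GC content to each named gene had a signed median of -0.0017 (-0.0082 to 0.0033). The named genes had 0.42. Such neighbours thus shared no shift on average. The test decides little more, since the named genes were picked as extremes. With an SD of 0.12 over well-counted genes, neighbours could hardly reach their size. DNA of another strain around Ccrl2 stays open. Of 89 genes within 5 Mb, 3 had an absolute log2 ratio of at least 0.5 (Mlh1 at -1.82, Dock3 at -0.53 and Nicn1 at 0.52). This share stood at percentile 93.8 of random sets, and Mlh1 lies 0.194 Mb from Ccrl2. Lrrfip2 (-0.41), among the 24 named genes but under the limit of 0.5, lies between Ccrl2 and Mlh1, at 111117592 to 111225668.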
